A study of Mus musculus with 4 samples.

How the data were processed

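Gene expression was measured by RNA sequencing in 4 cultures of C2C12 myotubes, which are the multinucleate muscle cells that the C2C12 mouse myoblast line forms in low serum. Per the labels, the cells grew in DMEM with 2% horse serum, RNA was taken with a phenol-based reagent, and libraries were made from poly(A) RNA with a strand-specific TruSeq kit. There were 4 groups with 1 library each: myotubes under EPS, a control for EPS, myotubes given clenbuterol and a control for clenbuterol. EPS is read here as electrical pulse stimulation, as is usual in work on cultured muscle, because the labels do not spell it out. The treatment field of all 4 libraries gives 30 ng/ml clenbuterol, controls included, so group membership was taken from the sample titles. Pulse settings and durations of either treatment are not given in the sources used here.

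The titles of the EPS pair conflict with the names under which its data were deposited. The record titled as the EPS control carries data named for EPS, and the record titled EPS carries data named for its control. The joint table of the series repeats the same values under the same data names. Groups follow the titles throughout, the 2 libraries are called "titled EPS" and "titled EPS control", and every EPS direction turns round if the data names are right. The values themselves were not used to decide between the 2 readings.

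The authors deposited, for each library, a table of coverage (mean read depth per base, a signal), FPKM and TPM per gene. They also deposited 1 table of the series with estimated read counts, FPKM and TPM for 45777 genes. Reads were aligned with HISAT2 to the mm10 mouse genome, per the submitters' processing notes, with no version stated. The program that computed the deposited estimated counts, FPKM and TPM, the annotation release and whether its counting used strand are not given in the sources used here. Deposited coverage times gene length divided by the deposited estimated count gave 101 bases, rounded to the nearest base, in 125 of 204 short single-transcript genes checked in the library titled EPS and another value in the rest. The counts are therefore treated as estimates, and how they were made is not stated. It is not stated whether mates or fragments were counted. If mates, the counting intervals are too narrow. TPM in the joint table and in the single tables differed by more than 0.001 for 1 to 3 genes per library. In each library 6 or 7 genes were listed at 2 places, and their rows were summed. Spreadsheet conversion had turned 26 gene symbols into dates, which were restored by gene ID from the RefSeq table of GRCm38.p6.

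Totals of estimated counts were 35597074 for the library titled EPS, 32640884 for the library titled EPS control, 33148483 for clenbuterol and 33408083 for its control. The main value was the log2 ratio of TPM with a pseudocount of 1, over genes with a TPM of at least 1 in at least 1 library of a pair. The pseudocount shrinks the ratios of weakly expressed genes. A gene counted as higher or lower when this ratio was at least 2-fold. For named genes the fold was also taken from CPM, the counts divided by library totals scaled by TMM factors (edgeR 4.0.16 in R 4.3.3), with an exact Clopper-Pearson 95% interval. These intervals and the floor of 3 counts for a library with no reads cover counting error only, not the spread between cultures. With 1 library per group no test between conditions could be run, and no p-value, standard error or standard deviation between cultures is given. All other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

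Before the data were examined, 39 gene lists were fixed for muscle, metabolism, stress, signalling and other cell types, and all 993 of their entries were found. For a list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Percentiles below 2.5 or above 97.5 are described as outside the middle 95% of random lists. Members of a real list can vary together while those of a random list are independent, so this describes these libraries and is not a test of the treatment. For the overlap of the 2 comparisons, the number expected of independent lists was also summed within groups of genes, split by type (protein coding, microRNA and snoRNA, other) and, in each type, into 10 equal groups by the highest count among the 4 libraries.

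The named genes are the 12 highest and 12 lowest TPM ratios of each treatment comparison among genes with a TPM of at least 5 in at least 1 library, leaving out predicted and unnamed loci. From each list described, up to 2 highest and 2 lowest members were added, together with Ppargc1a and 1 further gene whose values are left out here. Other genes named were chosen after their values were seen, and the text says so. The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter at a TPM of 5, ratios centred on the median gene, FPKM, CPM with TMM factors, the highest row in place of the sum, mitochondrial genes left out, and random lists without matching. After the data were seen 4 more were added: a 2-fold difference in TPM and in CPM together, protein-coding genes only, a 2-fold distance from each of the other 3 libraries, and the EPS titles exchanged.

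The calculation was tested on simulated data with Poisson counts at the means of the control library of each pair and 200 genes changed by a known fold. The changed genes were drawn only from those with a TPM of at least 5 and at least 20 counts in that control. Each gene's TPM per count was taken from the control, so shifts of reads between transcripts were not simulated. Genes with 0 counts in the control stayed at 0 in both simulated libraries. The numbers of unchanged genes below therefore leave out the counting noise of such genes. In simulated clenbuterol data of 13642 genes, 65 unchanged genes came out at least 2-fold apart in TPM by counting noise alone and 0 in TPM and CPM together. In simulated EPS data of 13677 genes the numbers were 62 and 0. Of genes changed 2.5-fold, TPM recovered 98.5% in the clenbuterol simulation and 100% in the EPS simulation. Both units together recovered 98.5% and 96.9%. This recovery does not extend to weaker genes. Among the real genes apart, 119 of 209 with clenbuterol and 142 of 278 under EPS had under 20 counts in the higher library. The counting intervals held the true fold in 95% and 94.5% of changed genes when the true library sizes were used. When sizes were taken as plain library totals, which the changed genes shift, they held it in 85% and 61.5%. The TMM scaling used for the real libraries was not itself part of this simulation. Of 200 random lists 5% fell outside the middle 95%.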

Results

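The series compared 2 in vitro models of exercise in C2C12 myotubes. In the first, cells received EPS, read here as electrical pulse stimulation, which makes cultured myotubes contract. In the second, they received clenbuterol, a sympathomimetic drug that acts through cyclic AMP. Each treatment had a control of its own, and each of the 4 groups held 1 library, so no value below has a replicate and differences are described by size. Total estimated counts per library ran from 32640884 to 35597074. Between 13412 and 13489 genes reached a TPM of 1. Folds are ratios of CPM, the counts scaled to equal library size, with a 95% counting interval unless TPM is named. The EPS titles conflict with the names of the deposited data, so the direction of every EPS difference below holds for the titles only.

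The first question was which transcripts differ in myotubes given clenbuterol. The clenbuterol library held more transcripts of Il6, of the 3 Nr4a genes and of CREB targets induced by cyclic AMP than its control. Il6, which encodes the cytokine interleukin-6 that working muscle secretes, had the largest ratio of TPM plus 1 among named genes with a TPM of at least 5. Its TPM was 50.4 with clenbuterol and 1.22 in the control, from 820 and 21 counts, a 40.2-fold difference (26.1 to 65.3). The 3 genes of the NR4A family of orphan nuclear receptors followed the same direction. Nr4a3 was 19.5-fold higher (17.0 to 22.5), Nr4a2 was 11.1-fold higher (9.98 to 12.4) and Nr4a1, the most abundant, was 6.51-fold higher (6.28 to 6.74) at a TPM of 629 against 97.4.

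Beyond those, the highest ratios belonged to the chemokines Cxcl1 and Cxcl5, to Il1rl1, Rgs2, Pde4b, Thbd, Ddit4 and Areg. Cxcl1 was 17.5-fold higher (9.56 to 35.7) on 187 counts against 11. Rgs2, a brake on G protein signalling, was 12.2-fold higher (8.80 to 17.3). Il1rl1, the receptor of interleukin-33, was 10.9-fold higher (8.15 to 14.8), and Cxcl5 was 8.73-fold higher (5.65 to 14.1). Pde4b, a phosphodiesterase that breaks down cyclic AMP, was 7.45-fold higher (6.41 to 8.70). Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, was 6.24-fold higher (4.62 to 8.56). Thbd, the thrombomodulin gene, was 5.99-fold higher (5.51 to 6.53). Ddit4, an inhibitor of mTOR complex signalling, was 5.50-fold higher (4.85 to 6.25), at a TPM of 64.8 against 11.96, but stood at 44.2 and 72.6 in the libraries titled EPS and EPS control, so that the control of clenbuterol was the library apart. Il6 lies on mm10 chromosome 5 at 30013114 to 30019975 and Nr4a3 on chromosome 4 at 48045078 to 48086447.

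**Figure D1:**
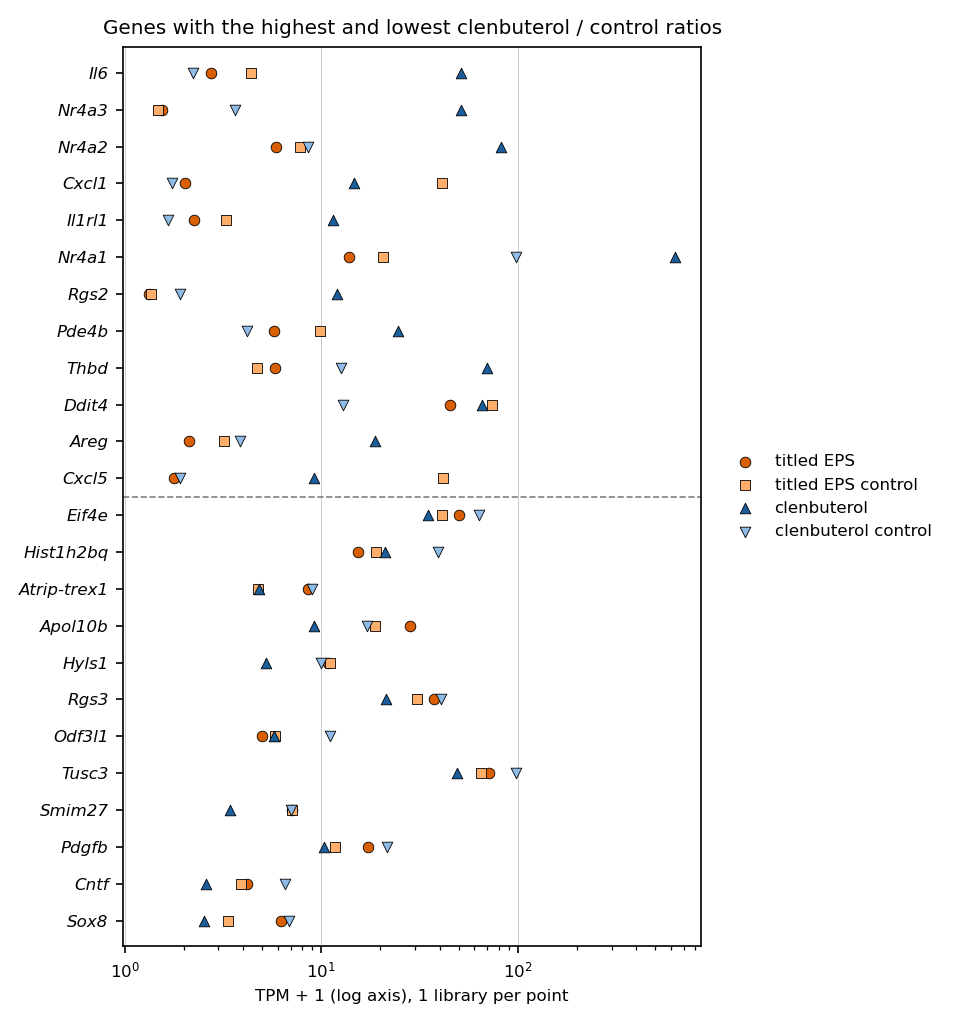
TPM plus 1 on a log axis in each of the 4 libraries, 1 point per library, for the 12 named genes with the highest (above the dashed line) and the 12 with the lowest clenbuterol to control ratio at a TPM of at least 5. Il6 stands at a TPM of 50.4 with clenbuterol and between 1.22 and 3.39 in the other 3 libraries.

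The gene lists placed this pattern among genes that respond to cyclic AMP and to acute stimulation. Of 19 measured CREB targets induced by cyclic AMP, 10 were at least 2-fold higher and 0 lower. Their median log2 ratio was 1.12, above all 10000 random lists. Of 28 immediate early genes 9 were at least 2-fold higher, with a median of 0.56 at percentile 100. The 2 lists share 5 genes, 4 of which were among those at least 2-fold higher. Klf10 (log2 −0.58) and Arc (−0.41) were the lowest immediate early genes. Of 16 genes of NF-κB and acute inflammation 4 were higher, with a median of 0.37, and of 23 myokines 4 were higher, with a median of 0.25. Without the filter on low values these medians were 0.07 and 0.10. Both filtered medians lay at percentile 100, and the 2 lists share 6 genes, 3 of which were at least 2-fold higher. At the low end of these 2 lists, Tnfaip3 stood at log2 −0.28 and Angptl4 at −0.46.

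Other lists held single genes that stood far from their list. Among clock genes, Per1, which cyclic AMP can induce directly, was 4.84-fold higher (4.53 to 5.18) while the list's median was 0.05 at percentile 96.5. Vegfa, the vascular growth factor gene, was 2.31-fold higher (2.24 to 2.38) in a list of 22 HIF-responsive genes with a median of 0.05. Its TPM was 288 with clenbuterol and 127 in the control, and 229 and 238 in the libraries titled EPS and EPS control. Irs2, an adaptor of the insulin receptor, was 2.67-fold higher (2.47 to 2.89), and Smad7, an inhibitor of TGF-β signalling, was 2.88-fold higher (2.64 to 3.13). In the list of undifferentiated myoblast genes, whose median was 0.20 at percentile 100, Hey1 was 5.99-fold higher (4.85 to 7.47) and Id3 was 3.27-fold higher (2.95 to 3.62). Btg2 and Plk3, counted among p53-responsive genes, were 3.78-fold higher (3.54 to 4.05) and 2.55-fold higher (2.36 to 2.77).

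Contractile and respiratory genes differed little. No measured gene of the fast fibre (15), slow fibre (14) or embryonic muscle (16) lists reached 2-fold, nor any of the 75 nuclear or 13 mitochondrial genes of the respiratory chain. List medians were −0.07, 0.02, −0.01, −0.01 and −0.03 in that order, and the nuclear respiratory chain median was 0.01 in CPM. Of these 5 medians only that of fast fibre genes lay outside the middle 95% of random lists (percentile 0.13), and it did not against random lists without matching (8.18). Ppargc1a, the coactivator that drives mitochondrial biogenesis, had a TPM of 1.69 with clenbuterol against 0.633 in the control. Its CPM was 1.89-fold higher (1.44 to 2.49), a smaller difference than that of its TPM without a pseudocount. The gene also belongs to the list of CREB targets induced by cyclic AMP.

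Outside the middle 95% of random lists but with medians no further from 0 than 0.07 were extracellular matrix (0.06), IGF and growth signalling (0.05), HIF-responsive (0.05), heat shock (0.05), glycolysis (0.04), cell cycle (−0.07) and YAP and SRF target genes (−0.07). Against random lists without matching, the growth signalling, HIF-responsive, heat shock, glycolysis and YAP and SRF target lists lay inside it. The lists inside that range were β-adrenergic machinery, PGC-1 and mitochondrial biogenesis, fatty acid oxidation, glycogen, myogenic regulators, atrophy and autophagy, excitation and calcium, ATF4 and unfolded protein response, NRF2 and antioxidant, interferon, p53, cholesterol, fatty acid synthesis, ribosomal protein, ribosome assembly, histone, osteoblast, fibroblast and apoptosis genes. Their medians ran from −0.06 to 0.05. Adipocyte markers and markers of immune, endothelial and neural cells had 2 measured genes each.

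Fewer genes were lower with clenbuterol than higher. Among named genes with a TPM of at least 5, Sox8, a transcription factor gene, had the lowest ratio and was 3.74-fold lower (2.84 to 4.98) at a TPM of 1.53 against 5.82. Cntf, which encodes ciliary neurotrophic factor, was 3.40-fold lower (2.21 to 5.38), and Gm44505, which overlaps Cntf on the same strand, had a TPM of 1.65 with clenbuterol and 0 in the control. Pdgfb, a platelet-derived growth factor gene, was 2.21-fold lower (1.97 to 2.48). Smim27, at 12 against 30 counts, was 2.43-fold lower (1.21 to 5.21). Hyls1, Apol10b and Rgs3 were 2.06-fold, 1.80-fold and 1.80-fold lower. Of the remaining genes with the lowest TPM ratios, Odf3l1 had 144 counts against 195, while Tusc3, Eif4e and Hist1h2bq had nearly equal counts in the 2 libraries (2324 and 2436 for Tusc3). Atrip-trex1, a read-through transcript, shares its place with Atrip, which differed the other way. Below a TPM of 5, and chosen after its values were seen, the desaturase gene Scd3 had 0 counts with clenbuterol and 144 in the control, at least 37.4-fold lower by its counting interval. Its paralogue Scd4, on the same strand nearby, stood the other way at 77 counts against 15 (5.28-fold higher, 3.01 to 9.89), and reads can be split between such copies.

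In all, 138 of 13788 genes were at least 2-fold higher in TPM with clenbuterol and 71 lower. In CPM alone these numbers were 62 and 19, and in both units together, a criterion added after the data were seen, they were 55 and 11. Most of the TPM differences lay in short or weakly expressed loci. Of the 209 genes 66 were microRNA or snoRNA genes, 119 had under 20 counts in the higher library, and 75 were protein coding.

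The second question was which transcripts differ under EPS. Read by title, the library titled EPS held fewer transcripts of the chemokine genes Cxcl1, Cxcl5, Ccl2 and Ccl7 and of NRF2 and antioxidant genes than the library titled EPS control. If the names of the deposited data are right, these genes were higher under EPS. Cxcl5 had a TPM of 0.780 in the library titled EPS and 40.7 in the library titled EPS control, a 48.8-fold difference (31.7 to 79.2). Cxcl1 was 36.6-fold lower by title (22.3 to 64.6), Ccl2 21.8-fold lower (15.5 to 31.5) and Ccl7 5.01-fold lower (3.83 to 6.63). All 4 encode chemokines that attract neutrophils or monocytes. Saa3, an acute phase gene, had 0 counts in the library titled EPS and 206 in the library titled EPS control, hence at least 61.3-fold lower by its counting interval and 76.1-fold lower against a floor of 3 counts. Nos2, the inducible nitric oxide synthase gene, was 9.47-fold lower (7.62 to 11.9), and F3, the tissue factor gene, was 4.57-fold lower (3.77 to 5.56). For Cxcl1, Cxcl5, Saa3 and Nos2 the library titled EPS control was the one apart, at least 2-fold above every other library in TPM plus 1. Ccl2 was at least 2-fold above every other library there and at least 2-fold below every other library in the library titled EPS. Ccl7 and F3 met neither condition.

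The other named genes with the lowest ratios were detoxifying and antioxidant genes. Hmox1, which encodes haem oxygenase 1 and lies on mm10 chromosome 8 at 75093618 to 75100593, had a TPM of 105 in the library titled EPS and 583 in the library titled EPS control. That was a 5.40-fold difference (5.18 to 5.63) on 2591 and 12626 counts, and the 2 clenbuterol libraries stood at 85.5 and 86.3. Gsta4 was 6.87-fold lower by title (6.10 to 7.77) and Aldh3a1 7.49-fold lower (5.62 to 10.2). For Hmox1 and Gsta4 the library titled EPS control was the one apart, at least 2-fold above every other library in TPM plus 1. For Aldh3a1 the library titled EPS was at least 2-fold below every other library. Gsta1 and Gsta2 were 13.6-fold and 51.0-fold lower, but these glutathione transferase genes are near-identical copies whose reads can be split between them.

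**Figure D2:**
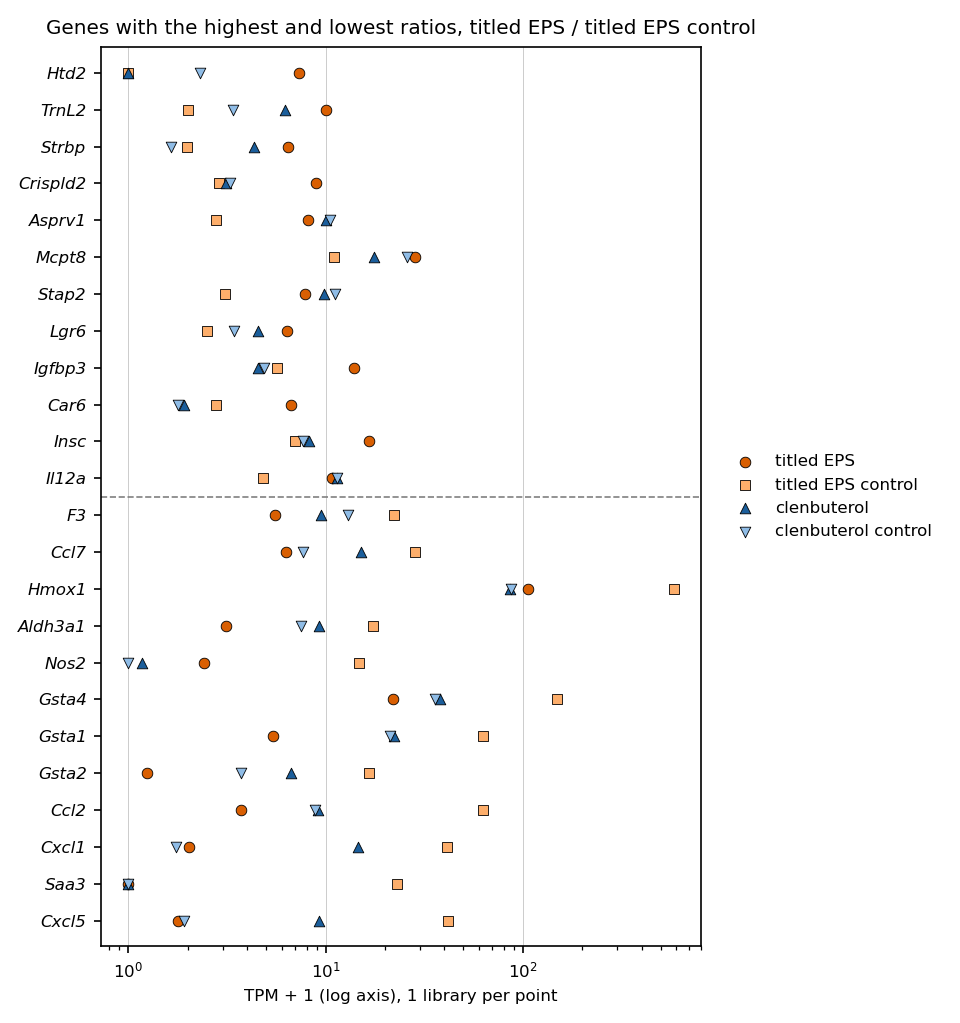
TPM plus 1 on a log axis in each of the 4 libraries, 1 point per library, for the 12 named genes with the highest (above the dashed line) and the 12 with the lowest ratio of the library titled EPS to the library titled EPS control at a TPM of at least 5. Hmox1 stands at 583 in the library titled EPS control and between 85.5 and 105 in the other 3 libraries.

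By list and by title, 9 of 26 NRF2 and antioxidant genes were at least 2-fold lower and 0 higher, with a median log2 ratio of −0.50. Among these, Mt1 and Mt2 are metallothionein copies of similar sequence. At the other end of that list stood Sesn2 (log2 0.52) and Gpx1 (0.18). Of 19 NF-κB and inflammation genes 7 were lower and 0 higher, with a median of −0.52 (−0.30 without the filter on low values and −0.32 at a pseudocount of 5), and Lif (0.38) and Cxcl10 (0.29) were its highest members. The median kept its place with Saa3 at its bound. Heat shock genes had a median of −0.28, and their lowest members Hspa1b and Hspa1a, which are also near-identical, were 2.58-fold and 2.51-fold lower. All 3 medians lay below every random list. Of 25 myokines 4 were lower and 2 higher, and the 4 lower ones also belong to the NF-κB list. Il15 was 3.02-fold higher (1.81 to 5.26), while Inhba was 2-fold higher in TPM and only 1.11-fold higher in counts (1.07 to 1.15). For Il15 the library titled EPS control was the one apart, at least 2-fold below every other library in TPM plus 1.

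Muscle lists also lay lower by title. All 14 slow fibre genes and all 16 embryonic muscle genes had ratios below 0, with medians of −0.47 and −0.44, below every random list. Myh7, the slow myosin heavy chain gene, was 2.39-fold lower (2.19 to 2.60), Ankrd2, a stretch-responsive gene, 1.96-fold lower (1.84 to 2.07) and Myh8, the perinatal myosin gene, 1.65-fold lower (1.58 to 1.72). The smallest differences in these lists were in Tnnc1 (log2 −0.08) and Tnnt2 (−0.03). Fast fibre genes had a median of −0.17 at percentile 0.16, with Myh2 1.58-fold lower (1.53 to 1.63) and Mylpf at log2 0.07. Excitation and calcium genes had a median of −0.21, atrophy and autophagy genes −0.20, glycolysis genes −0.24, HIF-responsive genes −0.20 and cyclic AMP targets −0.38, each below every random list. The glycolysis and HIF-responsive lists share 5 genes, Slc2a1 and Hk2 among them. Slc2a1, the glucose transporter of many cell types, and Hk2, a hexokinase gene, were 1.87-fold lower (1.82 to 1.93) and 1.85-fold lower (1.78 to 1.92). β-adrenergic machinery (−0.20), clock (−0.16) and myogenic regulator genes (−0.14) were below the middle 95%. The β-adrenergic median was −0.06 without a filter and −0.05 in FPKM, and myogenic regulators lay at percentile 5.89 against random lists without matching. Ppargc1a stood at a TPM of 0.291 in the library titled EPS and 0.256 in the library titled EPS control.

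On the opposite side, all 13 mitochondrially encoded genes were higher by title, with a median log2 ratio of 0.22 and ND5 the highest at 0.35. Ribosomal protein genes were higher in 70 of 75 cases, with a median of 0.11, and nuclear respiratory chain genes in 59 of 75, with a median of 0.12. In FPKM these 2 medians were 0.17 and 0.18, and that of undifferentiated myoblast genes, 0.21 in TPM, was 0.35. Undifferentiated myoblast genes (0.21), cell cycle (0.11), cholesterol (0.11), interferon (0.10), YAP and SRF target (0.10), histone (0.12) and osteoblast genes (0.29) also lay above the middle 95%. The histone list holds replication-dependent genes, whose transcripts lack a poly(A) tail in dividing cells. Histone values in these poly(A) libraries may therefore not follow transcript abundance. The list of 5 osteoblast genes includes Spp1, which myotubes express at a TPM above 1000 here. Immediate early genes (−0.08), myokines (0.00), PGC-1 (−0.14), fatty acid oxidation (0.06), glycogen (−0.14), growth signalling (−0.10), ATF4 (0.04), p53 (−0.06), matrix (−0.03), fatty acid synthesis (−0.03), ribosome assembly (−0.02), fibroblast (−0.09) and apoptosis genes (−0.02) lay inside it. In CPM the glycolysis median was −0.15.

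The named genes with the highest ratios by title were weakly expressed. Crispld2, a secreted glycoprotein gene, was 4.39-fold higher (3.56 to 5.45) and Asprv1 4.08-fold higher (2.86 to 5.97). Lgr6, Car6, Igfbp3, Mcpt8, Il12a, Insc and Stap2 were 2.30-fold to 3.24-fold higher. Igfbp3, a carrier of insulin-like growth factors, had a TPM of 12.9 in the library titled EPS and between 3.55 and 4.65 in the other 3. Ccn2, the connective tissue growth factor gene and highest of the YAP and SRF targets, was 2.21-fold higher (2.16 to 2.27) at a TPM of 576 against 267. For Ccn2, Asprv1, Il12a and Stap2 the library titled EPS control was the one apart, at least 2-fold below each of the other 3 in TPM plus 1. TrnL2 rested on 10 counts against 1 (a 9.02-fold ratio, 1.28 to 392). Strbp was 3.23-fold higher in TPM plus 1 but had 339 counts against 236. Htd2 had 245 counts against 0, at least 59.5-fold higher by its counting interval and 73.7-fold higher against the floor, and is listed at the same mm10 place and strand as Rpp14, so that reads can pass between the 2 genes.

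In all, 120 of 13828 genes were at least 2-fold higher in TPM in the library titled EPS and 158 lower. In TPM and CPM together these numbers were 29 and 67. Of the 278 genes 85 were microRNA or snoRNA genes, 142 had under 20 counts in the higher library and 114 were protein coding.

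**Figure D3:**
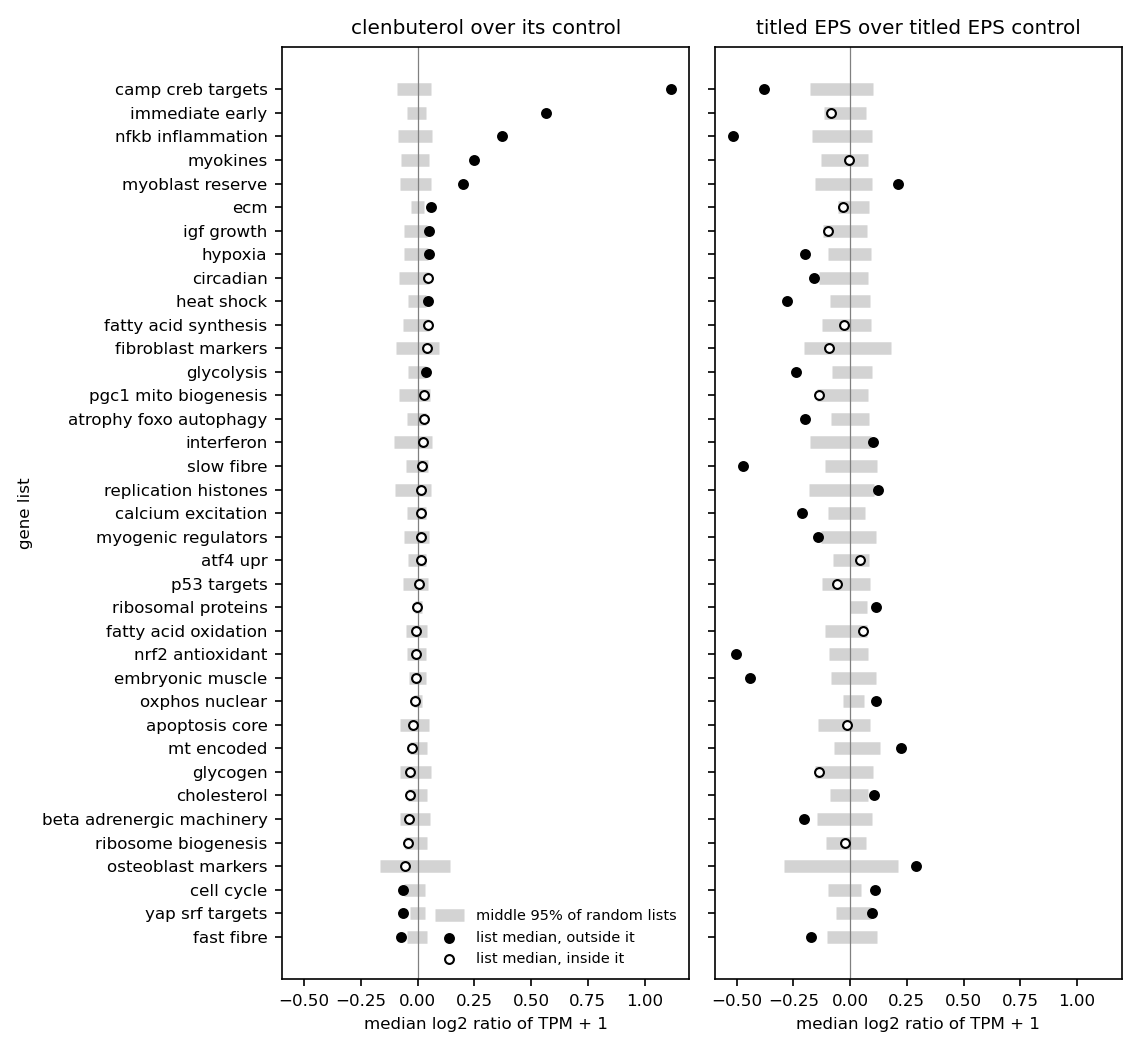
Median log2 ratio of TPM plus 1 for the 37 gene lists with at least 5 measured members, for clenbuterol over its control (left) and the library titled EPS over the library titled EPS control (right). Grey bars span the middle 95% of 10000 random lists matched on expression. Filled points lie outside it, with cyclic AMP targets highest on the left at 1.12 and NF-κB genes (−0.52) and NRF2 and antioxidant genes (−0.50) lowest on the right.

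The third question was whether the 2 models share differences. Across 11227 genes with a TPM of at least 5 in at least 1 library, the log2 ratios of the 2 comparisons had a Pearson r of −0.07 and a Spearman rho of −0.06, over genes, which are not independent replicates. With the EPS titles exchanged the same value is 0.07. The 2 comparisons share no control library. Among 13403 genes measured in both, 16 were at least 2-fold higher in both by title, against 0.652 for independent lists, and 8 were lower in both, against 0.440. In opposite directions stood 11 genes higher with clenbuterol and lower in the library titled EPS, against 0.836, and 3 the other way, against 0.343. Independent lists treat every gene as equally likely to be apart, while the genes apart were mostly weakly expressed, so the excess is not a measure of shared differences. Within groups of genes alike in type and count, a comparison added after the data were seen, the 4 expected numbers were 5.53, 3.27, 4.57 and 4.27. The observed 16, 8 and 11 still lay above these, and the observed 3 lay below. The cause of the remaining excess was not tested. Of the 16 genes 11 were microRNA or snoRNA genes and 2 protein coding. In TPM and CPM together the 4 observed numbers were 1, 3, 6 and 1. Chosen after their values were seen, the 6 were Abi3, Ankrd33b, Atrip, Cxcl1, Cxcl5 and Fgf7. They stood higher in the clenbuterol library and in the library titled EPS control than in the partner of each. Il6 was not among them, with a TPM of 1.76 in the library titled EPS and 3.39 in the library titled EPS control.

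A last comparison set the 2 control libraries against each other. They differed more than either treated library did from its own control, most of all in genes that respond to low oxygen. Between the library titled EPS control and the clenbuterol control, 257 of 13880 genes were higher and 180 lower, or 149 and 90 in TPM and CPM together. All 23 HIF-responsive genes were higher in the library titled EPS control and 11 were at least 2-fold higher, with a median log2 ratio of 1.00. The next 4 genes were chosen after their values were seen. Ero1l, an oxidase of the endoplasmic reticulum, was 5.76-fold higher (5.44 to 6.10). Bnip3, a mitophagy receptor gene, was 4.23-fold higher (4.02 to 4.45), and Slc2a1 was 3.96-fold higher (3.80 to 4.13). Txnip, whose transcript follows glucose supply, was 17.6-fold lower (15.4 to 20.2).

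**Figure D4:**
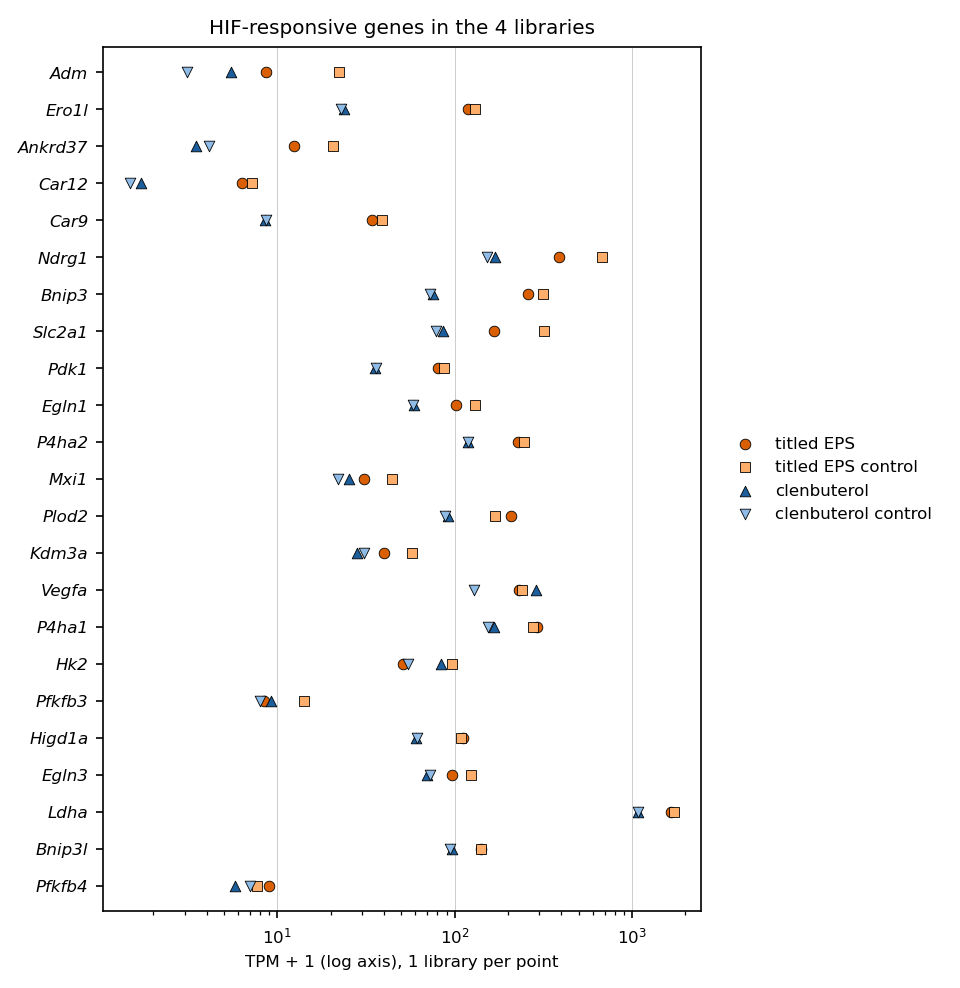
TPM plus 1 on a log axis in each of the 4 libraries, 1 point per library, for the 23 HIF-responsive genes. In 20 of the 23 both libraries of the EPS pair stand above both libraries of the clenbuterol pair.

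Glycolysis (0.59), ATF4 and unfolded protein response (0.53), NRF2 (0.50), matrix (0.47), cell cycle (0.37) and myokine genes (0.36) were also higher in the library titled EPS control, each at percentile 100. The glycolysis list shares 5 genes with the HIF-responsive list. NRF2 genes stood at −0.50 in the library titled EPS over that control. For the EPS pair against the clenbuterol pair, their median was only 0.09 at percentile 93.4. Histone (−0.55), fast fibre (−0.38), embryonic muscle (−0.38) and immediate early genes (−0.36) were lower in the library titled EPS control, each at percentile 0. The poly(A) limit on histone values given above holds here too. In this comparison 23 of 37 lists lay outside the middle 95% of random lists. Had the EPS titles been exchanged, the control pair would differ in 408 genes. All 4 comparisons across the pairs gave more genes than both comparisons within a pair.

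**Figure D5:**
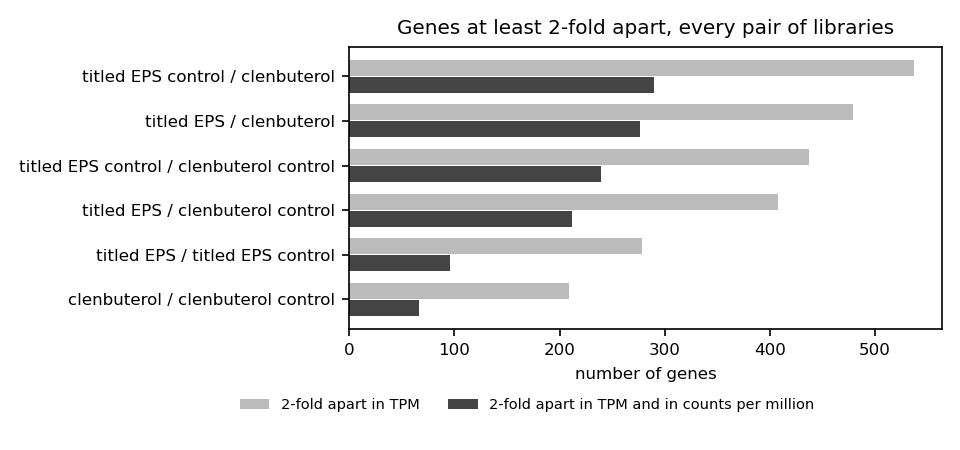
Number of genes at least 2-fold apart in each of the 6 pairs of libraries, in TPM (grey) and in TPM and CPM together (dark). The within-pair comparisons hold 209 and 278 genes in TPM, and the 4 comparisons across the pairs hold between 408 and 537.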

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

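The test of exchanged titles was chosen only after its result was seen, as was the criterion of a 2-fold difference in TPM and in CPM together.

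In 7 genes the library given clenbuterol and the library titled EPS lay at least 2-fold from their controls in opposite directions, in TPM and in CPM. The chemokine genes Cxcl1 and Cxcl5 had the largest gaps. The log2 ratio of Cxcl1 was 3.06 with clenbuterol and −4.34 by title under EPS, a difference of 7.40. That of Cxcl5 was 2.26 and −4.55, a difference of 6.81. Abi3, an actin regulator gene, stood at 2.14 and −2.45, a difference of 4.59. It overlaps Phospho1 on the opposite strand, and whether the counting used strand is not stated, so reads may have passed between the 2 genes. The growth factor gene Fgf7 stood at 1.24 and −1.25, a difference of 2.49, and Ankrd33b at 1.15 and −1.18, a difference of 2.32. Atrip stood at 1.03 and −1.15, a difference of 2.18. It overlaps Atrip-trex1, which differed the other way in both pairs (TPM 3.82 and 8.02 with clenbuterol and in its control, 7.58 and 3.77 in the libraries titled EPS and EPS control). Htd2 stood at −1.21 and 2.87, a difference of −4.08, and shares its place and strand with Rpp14. The differences between the 2 comparisons were not tested, since each group holds 1 library.

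An exchange of the EPS titles may account for these opposite directions, but the 7 genes were chosen for their opposite signs, so that an exchange aligns them by construction. It would set opposite the 4 genes that now differ the same way in TPM and CPM (H2-Q6, E130102H24Rik, Gm20056 and Gm38431). Of these, Gm20056 and Gm38431 overlap other genes on the same strand. Over all genes apart in both comparisons 24 of 38 had the same direction by title. Of the 24, 16 were higher in both, and 11 of these were microRNA or snoRNA genes. With protein-coding genes only the number was 2 of 10, in TPM and CPM together 4 of 11 and in CPM 7 of 15. The side thus turned with the setting, and the stricter sets hold few genes, so these numbers do not decide between the readings. The library titled EPS control held 40 genes at least 2-fold above each of the other 3 libraries, and the library titled EPS held 23. A treated library need not hold more such genes than a control. In TPM alone, 11 and 3 genes lay in opposite directions, against 4.57 and 4.27 within groups of genes alike in type and count. Reads shared with overlapping genes may enter for Abi3, Atrip and Htd2. From 1 library per group, a wrong title, a difference between cultures and a true opposite response cannot be told apart. The biological explanation, that EPS and clenbuterol act oppositely on the 7 genes, stays open and untested.

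A few genes at least 2-fold apart in TPM had CPM less than 25% apart, 4 in each comparison. Whether the authors' TPM moved reads between transcripts of 1 gene cannot be told. All 8 genes (100%) have more than 1 listed transcript, but of single-transcript genes with at least 20 counts 0 of 3986 with clenbuterol and 0 of 4033 under EPS had TPM and CPM ratios far enough apart to enter this group, so its choice fixes that share. The median count in the higher library was 481.5 with clenbuterol and 1393 under EPS, over 4 genes each, against at most 15 for the others. The choice of genes with close CPM leaves out those whose counts are apart through counting noise. These medians therefore describe the 8 genes and do not decide on low counts as a cause. No biological explanation was tested.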

How the results depend on the processing

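Of the alternatives below, 4 were chosen only after the data were seen: a 2-fold difference in TPM and CPM, protein-coding genes only, a 2-fold distance from each of the other 3 libraries, and exchanged EPS titles. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out.

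Of 6802 values of named genes under the alternatives 6476 moved by less than their counting interval, 326 moved further and 0 reversed. Filters and the restriction to protein-coding genes leave a gene's own value unchanged, and genes with no reads in 1 library always counted as unmoved. A reversal was counted only for ratios of at least 2-fold. Exchanged EPS titles, which turn every EPS value, were applied neither to these values nor to the list medians. Of 732 list medians 711 moved little and 21 moved further. Of 118 counts, overlaps and correlations 59 stayed within range, 58 moved and 1 reversed. Centring subtracted medians of −0.01, −0.02 and 0.04 from the clenbuterol, EPS and control ratios. With centred ratios, the highest row per gene or mitochondrial genes left out, every count of genes stayed within 1.5 times its value. The number of lists outside the middle 95% ran from 12 to 15 with clenbuterol and from 21 to 24 under EPS against matched random lists, and was 7 and 23 against random lists without matching. Where no reason is given below, the cause was not tested.

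The counts of genes depended on how weakly expressed genes were treated. With a pseudocount of 0.1, 256 genes were higher and 194 lower with clenbuterol, 220 higher and 351 lower by title under EPS, and 866 apart between the controls, while 101 overlapped, 59 in the same direction. With a pseudocount of 5 these numbers were 41 and 2, 9 and 36, 109, 2 and 0. With a filter at a TPM of 5, which compares fewer genes, they were 64 and 12, 43 and 69, 262, 9 and 4. In FPKM they were 54 and 10, 38 and 59, 178, 8 and 4, with a correlation of −0.10 (−0.103). In CPM they were 62 and 19, 42 and 80, 288, 15 and 7. Without a filter the counts of genes are unchanged by construction, and the correlation was −0.01 (−0.0101).

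With protein-coding genes only, which also compares fewer genes, 65 were higher and 10 lower with clenbuterol, 39 higher and 75 lower by title under EPS, 287 apart between the controls and 10 overlapping, 2 in the same direction, with a correlation of −0.11 (−0.1105). In TPM and CPM together, a stricter criterion, 55 were higher and 11 lower with clenbuterol, 29 higher and 67 lower under EPS, 239 apart between the controls and 11 overlapping, 4 in the same direction. At least 2-fold from each of the other 3 libraries stood 63 above and 13 below for clenbuterol, and 23 above and 28 below for the library titled EPS. With the EPS titles exchanged, 14 overlapping genes had the same direction and the correlation reversed to 0.07 (0.0718), by construction.

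The median of cyclic AMP targets with clenbuterol was 1.28 at a pseudocount of 0.1, 1.01 at a pseudocount of 5, 1.01 without a filter, 1.52 with a filter at a TPM of 5 and 1.36 in FPKM. That of NF-κB genes under EPS was −0.32 at a pseudocount of 5, −0.30 without a filter and −0.36 with a filter at 5, and with clenbuterol it was 0.07 (0.0725) without a filter. Myokines with clenbuterol had a median of 0.10 without a filter, 0.17 in CPM and 0.15 without mitochondrial genes. β-adrenergic genes under EPS had −0.06 (−0.0614) without a filter and −0.05 (−0.0512) in FPKM. In FPKM the EPS medians of nuclear respiratory chain, glycolysis, undifferentiated myoblast and ribosomal protein genes were 0.18, −0.14, 0.35 and 0.17. In CPM glycolysis had −0.15 under EPS, and nuclear respiratory chain and ribosomal protein genes had 0.01 (0.00762) and 0.02 (0.0189) with clenbuterol, where both were slightly below 0 in TPM.

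Against random lists drawn from all genes without matching, 7 lists no longer lay outside the middle 95%. With clenbuterol these were glycolysis (94.5), fast fibre (8.18), growth signalling (97.4), heat shock (96.9), YAP and SRF target (4.17) and HIF-responsive genes (96.5), and under EPS myogenic regulators (5.89). Depth limits the weakly expressed genes: the higher library had a median count of 10 among genes apart with clenbuterol and 16 under EPS.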

Other observations

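The test of library size was chosen only after its result was seen.

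The 2 libraries of the EPS pair, whichever of them was stimulated, stood together against the 2 libraries of the clenbuterol pair in genes that respond to low oxygen. Of 23 HIF-responsive genes 20 were higher in both libraries of the EPS pair than in both of the clenbuterol pair, 0 were lower in both, and the median difference was 1.97-fold. The 4 genes named next were chosen after their values were seen. Apln, a HIF target outside that list, had a TPM of 13.3 and 12.8 in the libraries titled EPS and EPS control against 0.799 and 0.913 with clenbuterol and in its control. Car9 stood at 33.0 and 38.0 against 7.50 and 7.61, and Ero1l at 118 and 130 against 22.7 and 21.8. Txnip stood the other way, at 4.12 and 5.75 against 93.7 and 98.4.

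Other gene groups separated the pairs too. ATF4 and unfolded protein response genes were higher in the EPS pair in 23 of 26 cases (median 1.45-fold), cell cycle genes in 35 of 38 (1.41-fold), matrix genes in 26 of 33 (1.33-fold) and ribosomal protein genes in 71 of 75 (1.17-fold). Embryonic muscle genes were lower in 13 of 16 cases (1.44-fold lower), fast fibre genes in 13 of 16 (1.35-fold lower) and histone genes in 19 of 27 (1.44-fold lower). Histone transcripts lack a poly(A) tail in dividing cells, so their values in poly(A) libraries may not follow abundance. Immediate early genes were lower in 17 of 28 cases (1.64-fold lower). Cyclic AMP targets were lower in 11 of 19 (1.65-fold lower) and higher in 1. Both lists were higher with clenbuterol than in its control, which enters these 2 medians. Of 14213 genes, 50 were at least 2-fold above and 29 at least 2-fold below in both libraries of the EPS pair.

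A hypothesis is that the 2 pairs came from cultures or batches that differed in oxygen, medium age or density. Which of these differed, if any, was not tested. The mean library totals of the pairs had a ratio of 1.03 against a 1.97-fold difference. That difference is in TPM, which is scaled to the same sum in every library, so the ratio of totals could not decide on it. The tables argue against a few genes taking most of the counts, since the share left after the 10 most abundant genes had a ratio of 1.01 between the pairs. In 59.8% of genes both libraries of 1 pair lay above both of the other, against 33.3% by chance and 19.2% and 20.7% for the other 2 ways of pairing the libraries. A batch that differed between the pairs may therefore be present, but pair and batch cannot be told apart, because the labels give no batch and each treatment had a control of its own.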
